A study of Mus musculus with 24 samples.

How the data were processed

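Mammary tumours of MMTV-PyMT mice were profiled by RNA sequencing of 24 libraries, 12 labelled KO and 12 labelled WT for Nr0b2. Per the labels' protocols, RNA came from frozen homogenised tumours and libraries were made with a stranded mRNA kit. The deposited counts are whole-number reads per gene, made with featureCounts 2.0.0 per the file headers on an annotation of GRCm39, and no strand option stands in those headers, so reads of overlapping and antisense genes cannot be told apart. The submitters' processing notes also name STAR and Subread, whose versions are not given in the sources used here. Reads placed at more than 1 position were not counted by the recorded command. The authors' deposited table gives log2 fold changes and log2 CPM, a signed fold and an F score, and p-values with adjusted p-values for the same comparison.

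Each count file holds 46318 gene IDs, of which 33552 had a read in some library. Symbols came from a RefSeq gene table for 44749 IDs and from the authors' deposited table alone for 13, and 1556 IDs had none. Coordinates are those of the count files. Groups came from the labels. No batch is labelled, KO numbers run from 1 to 12 and WT numbers from 13 to 24, and processing order cannot be told from genotype. Among 132 pairs of libraries within a group, the lowest chi-square per degree of freedom was 25.8, so no pair agreed within sampling noise.

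Counts were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, two-sided, Benjamini-Hochberg threshold 0.05) in R 4.3.3. Panel genes that failed the filter, Nr0b2 and Foxp3 among them, were added in an extended fit. List scores were the mean centred log2 CPM (prior count 2) of tested members, compared by a two-sided permutation test with 100000 resamples and adjusted over 41 lists with at least 3 tested members. The Foxp3 to Cd3e ratio used a pseudocount of 0.1 CPM. Correlations used 100000 resamples and their difference 20000. Fisher's exact test compared calls within 10 Mb of the Nr0b2 start with all others. Parents of 287 tested pseudogenes were sought with blastn 2.17.0 among GENCODE transcripts of GRCm38, by sequence and not by position, or from the symbol, and were found for 251. Those of 91 tested transcribed pseudogenes were sought afterwards, and for 32 none was found.

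Named genes followed a rule fixed, like the lists, designs and most alternative settings, before the data were examined: Nr0b2, the 10 largest rises and falls past the threshold at a mean of at least 1 CPM, the 5 smallest p-values in each direction not yet named, up to 4 members of each list, a fixed panel, and up to 10 calls near Nr0b2. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, robust dispersion, no filter and a stricter filter, adipocyte and muscle or B cell scores as covariates, surrogate variables (sva 3.50.0), other thresholds, camera, fry, other windows and leaving out each library. On simulated counts for the KO versus WT comparison over 15685 genes with 50 genes changed per fold size, 64% of 1.5-fold, 86% of 2-fold, 90% of 4-fold and 100% of 8-fold changes were recovered with 4 false calls, and a simulation without changes gave 0 calls. In simulated lists of independent genes, 5 of 5 shifted and 1 of 35 unshifted lists were called. Members of real lists were correlated, at up to 0.958 for skeletal muscle markers, so this does not give the recovery of such lists. Intervals and floors cover counting error only.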

Results

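Gene expression was measured by bulk RNA sequencing in mammary tumours of MMTV-PyMT mice, a strain in which the polyoma middle T oncogene is expressed in the mammary epithelium and tumours form spontaneously. The labels name 12 tumours as knockout (KO) and 12 as wild type (WT) for Nr0b2, which encodes the orphan nuclear receptor SHP, a repressor of bile acid synthesis genes. Tumours were collected at a volume of 2000 mm3. Library totals ran from 18789250 to 38022182 counted reads, and a count of 3 in a library corresponds to between 0.0789 and 0.16 CPM. Whether each tumour came from a separate animal is not stated, so the p-values measure the spread between these tumours.

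The targeted gene was examined first, because its level checks the genotype labels. Nr0b2 (chromosome 4, 133280687 to 133283997, plus strand, GRCm39) went against them: all 12 libraries labelled KO held reads, and 11 of the 12 labelled WT held none. The libraries labelled KO held 182 Nr0b2 reads together, from 3 to 71 each, and those labelled WT held 1. Scaled by library totals, the rate was 195 times higher in the libraries labelled KO (95% exact interval 34.6 to 7742, counting error only). The size of this ratio depended on 2 libraries. Without KO 12, which held 71 of the reads, it was 127. Without WT 24, which held the 1 WT read, it was 59.8 against an assumed floor of 3 reads over the group labelled WT. The exact 95% lower bound was then 48.2, counting error only. In the edgeR quasi-likelihood fit the adjusted p was 7.45e-05, with the gene added to the fit because it failed the expression filter. Gene-level counts do not show which part of the gene the reads came from, so reads from an undeleted part of a targeted allele are counted like any others. For this reason the groups are called the libraries labelled KO and labelled WT, and every direction given here follows those labels and not a measured loss of Nr0b2.

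**Figure D1:**
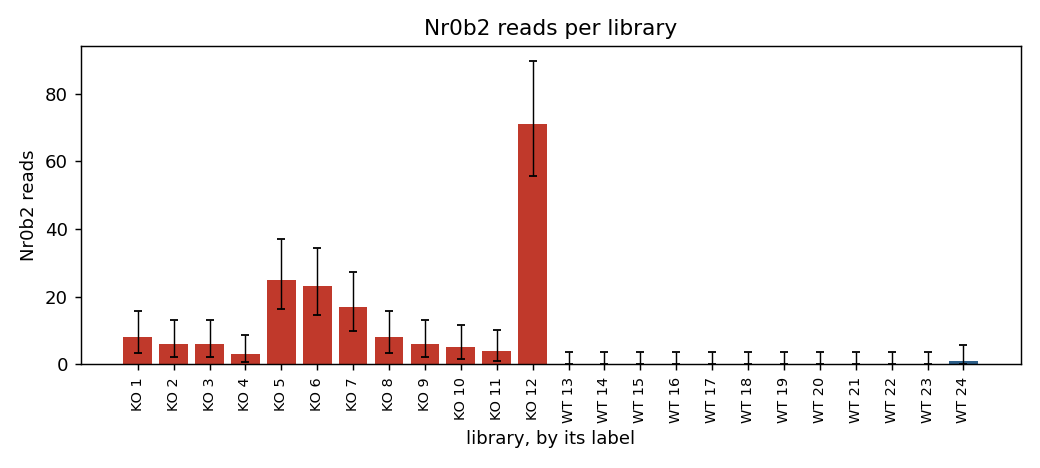
Nr0b2 reads (vertical axis) in each of the 24 libraries, named by label, with 95% exact Poisson intervals as bars. All 12 libraries labelled KO lie between 3 and 71 reads, and the highest library labelled WT holds 1.

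The design's comparison asks which genes differ between tumours with and without Nr0b2. The most significant differences were in pseudogenes, all higher in the libraries labelled KO. Hdac1-ps averaged 14.5 ± 4.54 CPM (SD, n = 12) against 0.75 ± 0.16 (n = 12), Gm10036 averaged 54.2 ± 35.3 CPM against 0.41 ± 0.20, and Nudc-ps1 averaged 12.6 ± 7.44 CPM against 0.16 ± 0.10. Gm6594, Gm10105 and Gm5824 also rose, by 8.11 ± 0.39, 6.67 ± 0.38 and 5.32 ± 0.38 on the log2 scale (SE). The ranges of these 6 pseudogenes did not overlap between the groups, which chance gives a gene in 7.4e-05% of cases. Among the calls, Smpdl3b, a phosphodiesterase-like gene of the cell membrane, was the other gene without overlap, and averaged 55.2 ± 18 CPM against 20.1 ± 6.22.

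Of 15820 tested genes, 50 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 28 higher and 22 lower in the libraries labelled KO. Most calls lay outside the Nr0b2 region, but nearly all of those passed only through adjustment together with the genes tied to it. Of the 50 calls, 11 lay within 10 Mb of Nr0b2, and 5 called pseudogenes have a parent gene there. With all genes of the window and all pseudogenes with a parent in it left out, a setting chosen after seeing the data, 1 gene of 15515 passed, the pseudogene Gm5824. The other 33 of the 34 calls outside the region therefore passed only when adjusted together with the genes of the region. At an unadjusted p under 0.05, 2893 genes outside the region were counted. DESeq2 called 418 genes, and leaving out single libraries gave between 9, without WT 18, and 72, without WT 14.

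Genes near Nr0b2 were called more often than other genes. Within 10 Mb, 11 of 298 tested genes passed (3.69%), against 39 of 15520 elsewhere (0.251%), an odds ratio of 15.2 (95% interval 6.95 to 30.7, Fisher's exact test, two-sided, p = 1.71e-09). The 11 became 7 without KO 5 or WT 13, 5 without WT 24, 4 without KO 7, KO 11 or WT 23, 3 without KO 10 or WT 17, and 2 without WT 18, where the odds ratio was 14.95 with the highest p of such fits, 0.0117. Of the 11, 6 were higher and 5 lower in the libraries labelled KO. Extl1, an exostosin-like glycosyltransferase gene, rose by 2.42 ± 0.35 (log2, SE; adjusted p = 0.000528 in edgeR) and Smpdl3b by 1.46 ± 0.19 (adjusted p = 6.65e-05 in edgeR), each above the WT median in 12 of 12 libraries labelled KO. The lysosomal fucosidase gene Fuca1 rose by 0.41 ± 0.09. The histone deacetylase gene Hdac1 averaged 70.2 CPM in the libraries labelled KO against 98.6, a log2 change of -0.49 ± 0.09, and the nucleosome-binding gene Hmgn2 averaged 113 CPM against 184.6, a change of -0.71 ± 0.14. Hdac1 and Hmgn2 have pseudogene copies among the calls that can share their reads. With the counts of parent and pseudogenes summed, a setting chosen after seeing the data, neither passed (adjusted p = 0.156 and 0.061). The changes were then -0.23 ± 0.08 for Hdac1 and -0.60 ± 0.14 for Hmgn2, the latter within its SE of the value alone. Of the other calls in the window, Gm34305 and Zbtb8os changed by 0.72 ± 0.15 and 0.41 ± 0.08, and Gm42323 and Gm33901 by -1.35 ± 0.28 and -3.04 ± 0.64. Gm33901 moved most with WT 13, at 6.50 CPM against a WT mean of 1.18: without it the change was -2.27 and did not pass. Leaving out single libraries, Smpdl3b and Extl1 passed in 24 of 24 fits, Hdac1 in 23, Hmgn2 in 16 and the other named genes of the window in 11 to 17. With the B cell covariate Smpdl3b, Extl1 and Hdac1 passed, and Hmgn2, Fuca1, Gm34305, Zbtb8os, Gm42323 and Gm33901 did not. With adipocyte and muscle covariates Fuca1 and Zbtb8os did not pass, nor did Fuca1 with chromosome medians as offsets.

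**Figure D2:**
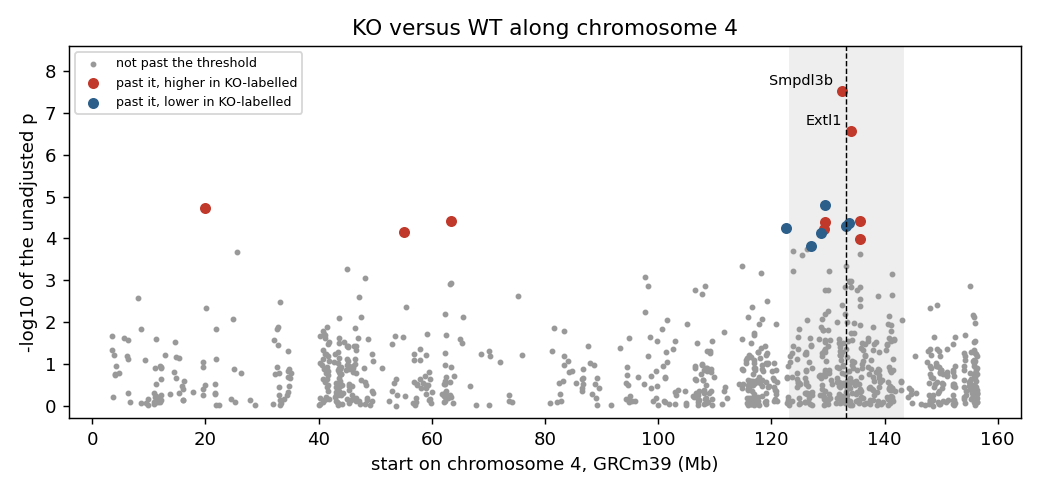
Unadjusted p on a -log10 scale (vertical axis) against gene start in Mb on chromosome 4 of GRCm39 for each tested gene. The dashed line marks Nr0b2, grey shading the 10 Mb on each side, and larger points the calls, of which 11 lie in the shaded window.

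**Figure D3:**
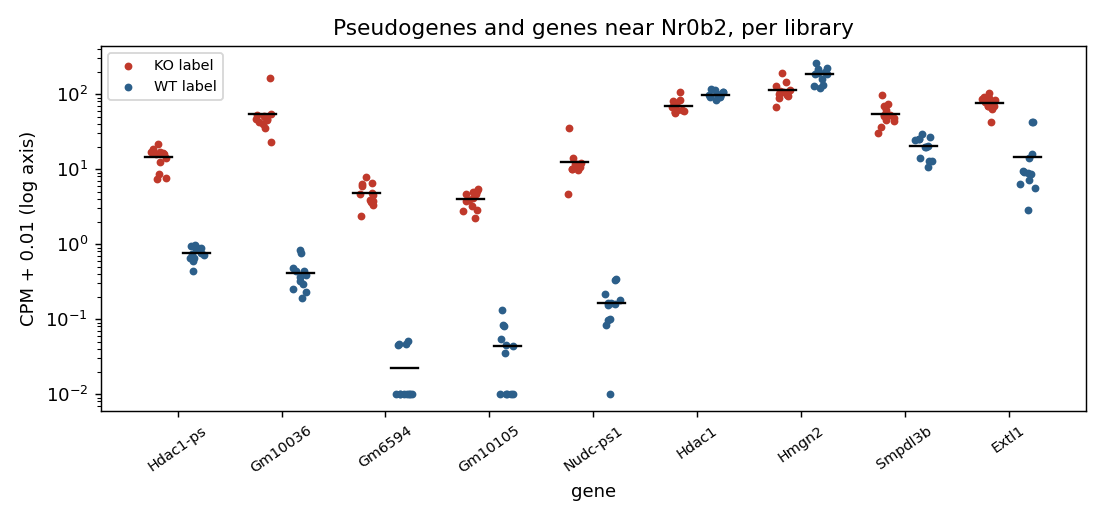
CPM plus 0.01 on a log axis for 5 called pseudogenes and 4 called genes near Nr0b2, with a point per library and a line at each group mean. The 5 pseudogenes and Smpdl3b do not overlap between the 12 libraries labelled KO and the 12 labelled WT.

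Outside the region and its pseudogenes, the largest rises included 2 milk genes, while the list of milk and alveolar genes was not called (score 1.31 ± 0.58 higher, adjusted p = 0.17, permutation test). Glycam1, a milk mucin, averaged 828 CPM in the libraries labelled KO against 1.21, and Csn1s2a, a casein, 704 CPM against 4.62, but library KO 7 alone held 9697 CPM of Glycam1 and 8256 CPM of Csn1s2a. Across fits leaving out single libraries the log2 change of Glycam1 ran from 4.16 to 9.74 and that of Csn1s2a from 1.86 to 7.86, both lowest without KO 7 and that of Csn1s2a highest without WT 17, and they passed in 11 and 10 of the 24 such fits. Tchh, a hair follicle protein gene, averaged 38.5 ± 67.6 CPM against 3.68 ± 2.52, with 239 CPM in library KO 12. Its log2 change was 3.38 ± 0.73 over all libraries and 2.45 without KO 12, and it passed in 7 of the 24 fits. Ttpa, the tocopherol transfer protein gene on chromosome 4, rose by 0.69 ± 0.13. Among the falls, Ppp1r1b, a phosphatase inhibitor gene, changed by -1.74 ± 0.34, Cnmd, which encodes chondromodulin, by -2.41 ± 0.53, and the transcription factor gene Lmx1b by -1.55 ± 0.35. C130021I20Rik, a non-coding gene at the start of Lmx1b on the other strand, changed by -1.87 ± 0.34. These 4 lay below the WT median in 12 of 12 libraries labelled KO. Further falls were those of Gm12873 (-3.68 ± 0.76), Slc16a11 (-2.72 ± 0.60), Pnmal2 (-1.83 ± 0.39), Ccbe1 (-1.33 ± 0.29), Dlec1 (-1.01 ± 0.21), Slc4a3 (-0.74 ± 0.15), Zfr2 (-0.59 ± 0.12) and Yeats2 (-0.39 ± 0.08), and Gm5088 and Larp1b rose by 1.54 ± 0.34 and 0.42 ± 0.08. Gm12873 starts at 122665268 on chromosome 4, just outside the 10 Mb window of Nr0b2 and inside one of 20 Mb. Slc16a11 moved most with WT 23, at 10.2 CPM against a WT mean of 2.13: without it the change was -2.11 and did not pass. Leaving out single libraries, Slc16a11 passed in 5 of 24 fits, as did Cnmd and Lmx1b, Gm5088 in 4, C130021I20Rik in 24, and the others of the falls, Ttpa and Larp1b in 8 to 20. In voom, Glycam1, Csn1s2a, Tchh, Cnmd, Slc16a11 and Lmx1b had log2 changes of 2.06, 1.72, 1.89, -1.13, -1.60 and -1.07 and did not pass, nor did Gm12873, Ppp1r1b, Pnmal2 and Yeats2. With adipocyte and muscle covariates, Cnmd, Tchh and Slc16a11 were at -1.77, 2.78 and -2.21 and did not pass, nor did Glycam1, Csn1s2a, Lmx1b, Pnmal2 and Ccbe1. With chromosome medians as offsets, Larp1b, which lies on chromosome 3, Gm5088, Slc16a11, Tchh, Cnmd and Lmx1b did not pass, and with the B cell covariate Ttpa and Zfr2 were the genes of this paragraph that passed. All genes named in this paragraph belong to the calls that end when the Nr0b2 region is left out.

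The series title speaks of myeloid cells and regulatory T cells, and 41 gene lists fixed before the data were examined were scored in each tumour. A permutation test called 2 lists after Benjamini-Hochberg adjustment, both higher in the libraries labelled KO. Camera with an estimated correlation called neither (adjusted p = 0.722 for both), and camera with a preset correlation called both. Tumour-associated macrophage genes scored 0.61 ± 0.17 higher (log2, SE, n = 12 per group, permutation p = 0.00152, adjusted p = 0.0312), above the WT median in 12 of 12. Of its 11 tested members 0 passed over all genes in edgeR, 2 passed adjusted over the list alone, and 6 were higher at an unadjusted p under 0.05. Spp1, which encodes osteopontin, averaged 4662 CPM against 1321, and the mannose receptor gene Mrc1 averaged 65.6 against 40.05. Bulk counts do not show which cells these reads came from, so the score cannot be read as an amount of macrophages. The list of pan macrophage markers was not called (adjusted p = 0.319, permutation test). Oxidative phosphorylation genes scored 0.28 ± 0.10 higher (permutation p = 0.00062, adjusted p = 0.0254), above the WT median in 11 of 12. All 12 tested members had a positive log2 change and 10 passed adjusted over the list alone, with 0 over all genes; Ndufb8 of respiratory complex I averaged 145 CPM against 112. Short genes tended higher in the libraries labelled KO, with a Spearman correlation of -0.339 between log2 change and length across genes, which are not independent replicates. Random lists matched to the oxidative phosphorylation genes on length and expression averaged 0.15, and the list lay at percentile 98.4 of them.

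Both calls depended on single libraries and on the test. With libraries KO 11 and KO 12 left out, a setting chosen after seeing the data, both adjusted p-values were 0.0898. The macrophage difference was then 0.55, near its size over all libraries, and that of oxidative phosphorylation fell from 0.28 to 0.16. The macrophage call ended without any of KO 7, KO 11, WT 17 or WT 23, with a highest adjusted p of 0.0572, and the oxidative phosphorylation call ended without WT 23, at 0.0508. In camera both were called with a preset correlation, with adjusted p = 0.00233 and 3.15e-06, while fry gave 0.0803 and 0.193.

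**Figure D4:**
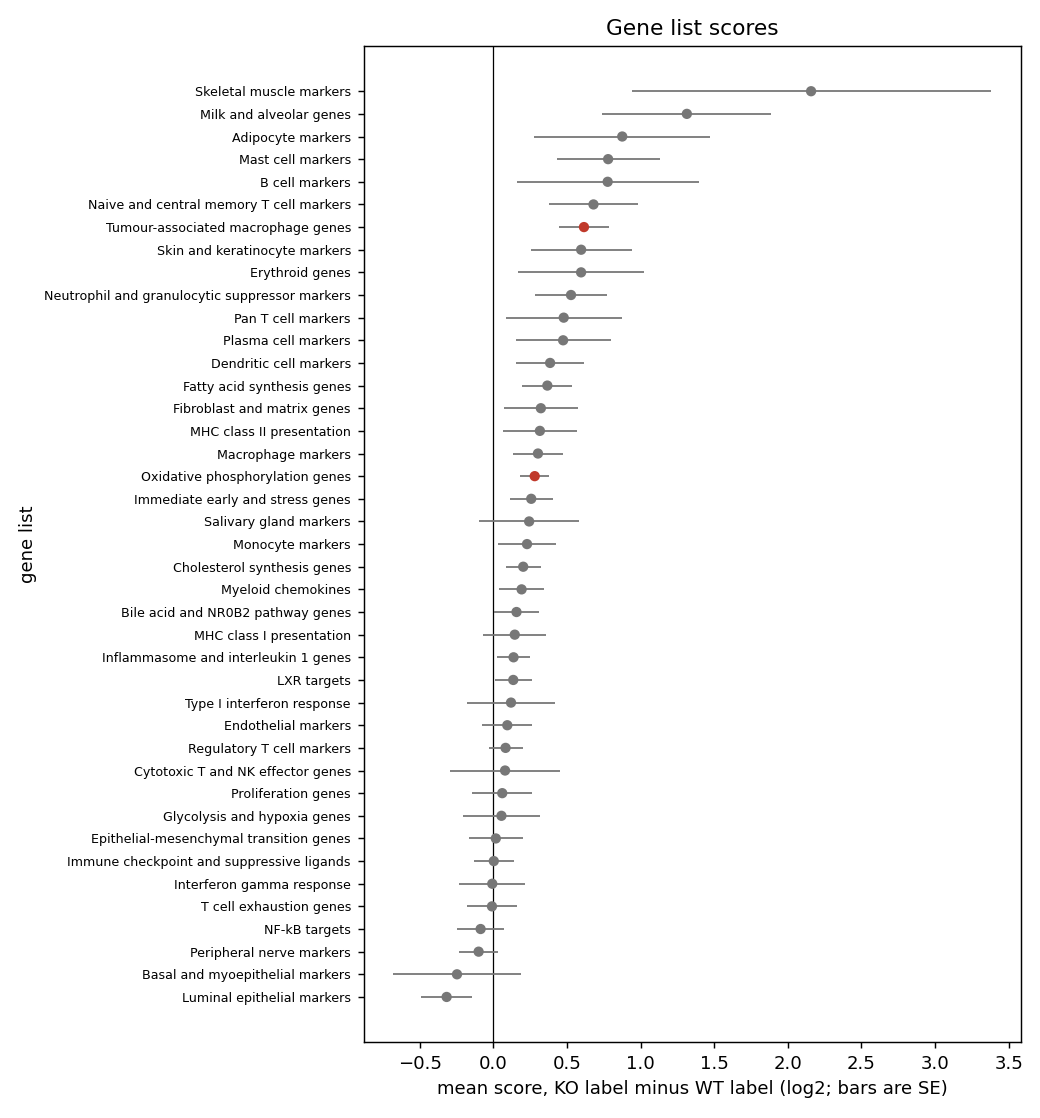
Difference in mean list score between libraries labelled KO and WT (horizontal axis, log2, 12 libraries per group) for 41 gene lists, with SE as bars. The lists called by the permutation test, in red, are tumour-associated macrophage genes at 0.61 and oxidative phosphorylation genes at 0.28.

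The tested regulatory T cell markers did not differ beyond the spread between tumours. Their score difference was 0.08 ± 0.12 (adjusted p = 0.689, permutation test), and 0 of 8 tested members passed in edgeR, over all genes or adjusted over the list alone. The score held 8 of the 14 listed markers. Foxp3, Ctla4 and Il10 failed the expression filter and were not in it, so it does not cover them. Foxp3, the lineage factor of these cells, changed by 1.26 ± 0.60 on the log2 scale (adjusted p = 0.255 in edgeR). It was near the detection limit, with 72 reads in the libraries labelled KO and 31 in those labelled WT. Of 24 libraries, 15 held 3 Foxp3 reads or fewer. Relative to Cd3e, a T cell receptor complex gene, Foxp3 differed by 0.32 on the log2 scale (permutation p = 0.456). The sign turned with a pseudocount of 0.5 CPM, at -0.0066, and with list scores in place of the genes, at -0.395. That score held no Foxp3, and this depth could not show a small difference. Ctla4, an inhibitory receptor gene, averaged 0.48 ± 0.37 CPM against 0.13 ± 0.11 and was above the WT median in 12 of 12, with an adjusted p of 0.0766 in edgeR. Pan macrophage markers differed by 0.30 ± 0.17 (adjusted p = 0.319), and Adgre1, Cd68, Nlrp3, Il1b and Cd274 had adjusted p-values from 0.55 to 0.98 in edgeR. Ccl2, Il10, Cd4 and Itgam, with log2 changes of 0.89 ± 0.29, 1.00 ± 0.38, 0.98 ± 0.40 and 0.58 ± 0.24, had adjusted p-values from 0.145 to 0.21. Il2ra, Cd8a, Tgfb1, the bile acid receptor gene Nr1h4, the cholesterol transporter gene Abca1 and the sterol hydroxylase gene Cyp27a1 had adjusted p-values from 0.50 to 0.994. Markers of other tissues varied widely: skeletal muscle scored 2.16 ± 1.22 higher and adipocytes 0.87 ± 0.60 higher, with adjusted p of 0.319 and 0.408, and Acta1 reached 1541 CPM in library KO 11.

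The relation of the regulatory T cell score to the macrophage score was computed within each group, 2 relations in all. The regulatory T cell score held 8 of 14 listed markers, without Foxp3, Ctla4 and Il10, so these relations do not include the lineage factor. In the libraries labelled KO the scores rose together, with Pearson r = 0.838 (n = 12, permutation p = 0.00075, adjusted p = 0.0015) and Spearman rho = 0.888 (permutation p = 0.00022). Without the 2 libraries farthest from the median macrophage score, r was 0.791 (permutation p = 0.00652). In the libraries labelled WT r was 0.424 (permutation p = 0.169, adjusted p = 0.169) and rho 0.336 (permutation p = 0.287), and r was 0.186 without the 2 farthest. The correlations differed by 0.414 (permutation p = 0.0409). With the monocyte list in place of the macrophage list, r was 0.735 in the libraries labelled KO (permutation p = 0.00619) and 0.674 in those labelled WT (permutation p = 0.0167), a difference of 0.0602 (permutation p = 0.776), so the difference between the groups depended on the list. With the pan T cell score subtracted from the regulatory T cell score, r with the macrophage score was -0.597 (permutation p = 0.0337) and -0.70 (permutation p = 0.0122). The pan T cell score varied more than the regulatory one, with an SD of 1.231 against 0.313 in KO and 0.588 against 0.246 in WT, so this sign can follow from the subtraction and says little about regulatory T cells.

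The authors' deposited table covers 14019 genes and holds 41 at its adjusted p under 0.05, 25 higher and 16 lower in KO. All 41 were among the 50 calls here, in the same direction, and the log2 changes correlated at 0.99995 across genes, which are not independent replicates. A filter of at least 1 CPM in at least 12 libraries left the same 14019 genes and called the same 41. Directions in the authors' deposited table thus follow the same labels.

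**Figure D5:**
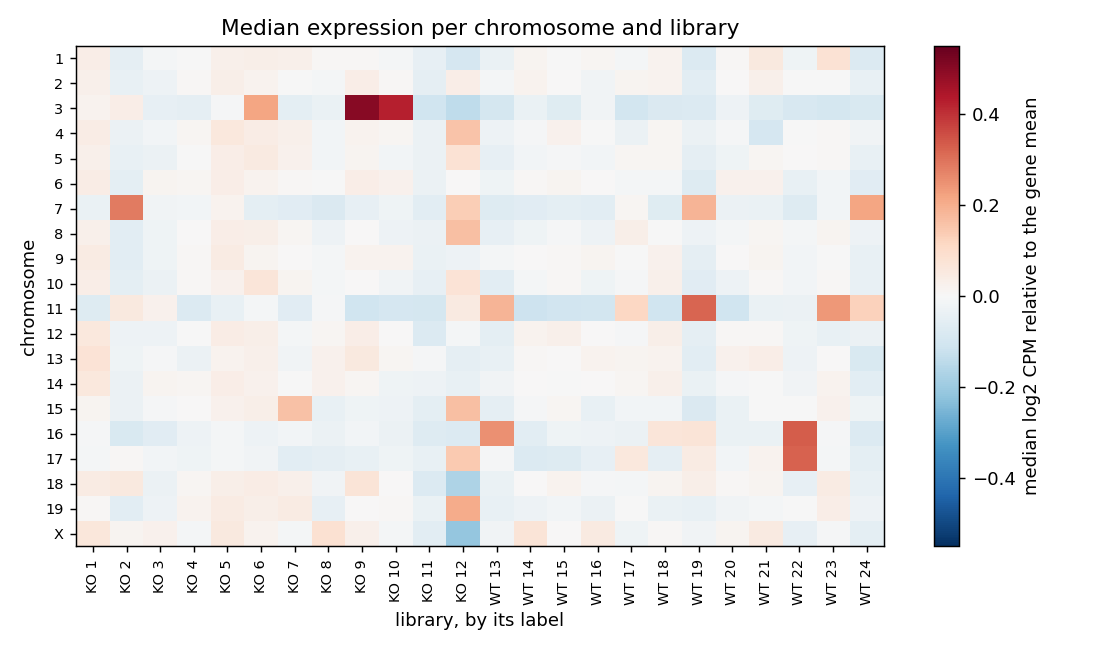
Median log2 CPM relative to each gene's mean over all libraries, per chromosome (rows) and library (columns), over genes at a mean of 5 CPM or more. Chromosome 3 reaches 0.50 in library KO 9 and 0.43 in KO 10.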

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

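The settings that leave out libraries KO 11 and KO 12 or the Nr0b2 region, the chromosome offsets, and the odds ratios near Nr0b2 without single libraries were chosen after seeing the data. The count of 50 genes stayed within 1.5 times under RLE and upper-quartile scaling, voom, robust dispersion, no filter and the stricter filter, sharing 50, 46, 30, 50, 31 and 41 of the 50 genes. It was 418 in DESeq2, 98 with adipocyte and muscle covariates, 13 with the B cell covariate, 10 with surrogate variables, 31 without KO 11 and KO 12, 32 with chromosome medians as offsets, 1 without the Nr0b2 region and its pseudogenes, 8 at adjusted p under 0.01 and 231 at 0.1. No filter gave 30 higher and 15 lower calls, and voom 47 and 22. The adipocyte and muscle covariates gave 62 higher and 36 lower, and DESeq2 204 and 214. The B cell covariate gave 11 higher and 2 lower, surrogate variables 9 and 1, and the fit without WT 18 gave 8 and 1. Leaving out single libraries gave 9 to 72. It was 31 without KO 5, 32 without KO 6, 18 without KO 7, 12 without KO 10, 15 without KO 11, 15 without WT 13, 30 without WT 15, 10 without WT 17, 9 without WT 18, 32 without WT 21, 27 without WT 22, 12 without WT 23 and 22 without WT 24. The loss without the region follows from its construction, since the smallest p-values leave the adjustment. For the others the cause was not tested. The 2 called lists became 14 in camera with a preset correlation, 0 with an estimated one, 0 in fry, 0 without KO 11 and KO 12, and 0 to 3 when single libraries were left out. Nr0b2 stayed higher in the libraries labelled KO and past the threshold, and calls near Nr0b2 stayed enriched with odds ratios of 2.62 to 46.62. Foxp3 relative to Cd3e was -0.0066 with a pseudocount of 0.5 CPM, -0.395 with list scores, and 0.176 to 0.568 leaving out single libraries. The correlation of regulatory T cell and macrophage scores was -0.597 (KO) and -0.70 (WT) with the pan T cell score subtracted, a sign that can follow from the subtraction. It was 0.674 in WT with the monocyte list. Shared genes with the authors' deposited table numbered 2576 at an unadjusted p under 0.05. Over 200 genes of the naming rule, 57 of 1400 alternatives had the opposite sign, 0 of them past the threshold; in 62 a called gene lost its call and in 14 another gained one. With the adipocyte and muscle covariates 31 of the 50 genes passed, and with the B cell covariate 13. Among named genes these were, for Cyp27a1, -0.245 with adipocyte and muscle covariates, -0.185 with the B cell covariate and -0.075 to 0.345 leaving out single libraries; for Cd8a, -0.123 in DESeq2, -0.429 in voom, -0.390 and -0.665 with those covariates and -0.102 to 0.812 leaving out libraries; for Cd274, -0.150, -0.124 and -0.096 to 0.212. Cd3e was -0.048 in voom and -0.281 with the B cell covariate, Cd68 -0.021 in voom, Acta1 -0.170 with adipocyte and muscle covariates, Tgfb1 0.0067 with adipocyte and muscle covariates and -0.050 to 0.053 leaving out libraries, and Il1b -0.0018 to 0.345. List scores crossed 0 leaving out libraries for cytotoxic T and NK effector genes (-0.087 to 0.232), T cell exhaustion (-0.084 to 0.045), NF-kB targets (-0.130 to 0.027), interferon gamma response (-0.083 to 0.125), checkpoint ligands (-0.046 to 0.086), glycolysis and hypoxia (-0.112 to 0.157), proliferation (-0.044 to 0.136) and epithelial-mesenchymal transition (-0.050 to 0.072). Checkpoint ligands were -8.1e-05 with a prior count of 0.5 and -0.014 without KO 11 and KO 12, where glycolysis and hypoxia genes were -0.107. Interferon gamma response turned upward in camera and fry, with adjusted p of 0.805, 0.955 and 0.886. No paired analysis was possible because the groups share no replicate numbers.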

Other observations

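The tests of the Nr0b2 reads, of pseudogenes and of summed parent and pseudogene counts, the choice to leave out the Nr0b2 region, and the enrichment near Nr0b2 without single libraries were chosen after the result was seen. Lists not called also had members that passed higher adjusted over the list alone: 4 of 5 mast cell markers, 4 of 7 naive and central memory T cell markers, 3 of 4 B cell markers, 5 of 5 erythroid genes, 8 of 10 skeletal muscle markers, 3 of 3 skin and keratinocyte markers, 6 of 10 milk and alveolar genes, 3 of 12 myeloid chemokines, 2 of 7 neutrophil markers and 1 of 9 monocyte markers. Single libraries stood out for some genes of these lists. Krt10 was at 137.2 CPM in KO 1, Csn2 at 16070 in KO 7 and Acta1 at 1541 in KO 11. The highest libraries labelled WT held 14.86, 73.01 and 152.8 CPM of these genes. Members of a list can rise together in 1 tumour, so the member counts are not independent evidence of a group difference. Cpa3, a mast cell protease gene, averaged 4.41 CPM against 1.69. The score p-values of these lists, adjusted over 41 lists, ran from 0.17 to 0.451. Luminal epithelial markers scored -0.32 ± 0.17 (adjusted p = 0.319), with 1 of 12 members lower adjusted over the list alone.

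Nr0b2 reads stood in 12 of 12 libraries labelled KO. A difference in depth is argued against by the lower bound of the rate ratio scaled by library totals, 34.6. Exchange of single libraries between the groups is argued against by 0 libraries labelled WT with 3 or more reads. An exchange of all labels and a transcript left from the targeted allele cannot be told apart, since both may give reads in all 12 and gene counts do not show where in the gene the reads lie. No direction in these data can therefore be read as an effect of losing Nr0b2 without reads over the deleted part.

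The pseudogene rises may come from reads of parent genes near Nr0b2 that carry variants against the reference and are placed on a closer-matching pseudogene. Among pseudogenes annotated as untranscribed, 5 of 7 with a parent within 10 Mb of Nr0b2 were called higher, against 0 of 244 with a parent elsewhere (Fisher's exact test, p = 2.63e-09) and 1 of 36 without a parent found. In this class the 0 argues against a change of pseudogenes wherever their parent lies. Only pseudogenes that passed the expression filter were counted. Gm6594 and Gm10105, at up to 0.041 and 0.12 CPM in libraries labelled WT, passed it through the libraries labelled KO. The 5 of 7 is therefore not the share among all pseudogenes with a parent there. These 2 also share Hmgn2 as parent, while the Fisher test counts them as separate. Among transcribed pseudogenes, 0 of 1 with a parent in the window, 1 of 58 with a parent elsewhere (Gm16016) and 1 of 32 without a parent found (Gm5088) were called higher, and Gm12873, without a parent found, was called lower. A change not tied to a parent near Nr0b2 stays open for these. Summing parent and pseudogene counts moved Hdac1 from -0.49 ± 0.09 to -0.23 ± 0.08 and Hmgn2 from -0.71 ± 0.14 to -0.60 ± 0.14 on the log2 scale. Both calls ended (adjusted p = 0.156 and 0.061), but the Hmgn2 change moved by less than its SE. In the libraries labelled KO its pseudogenes Gm6594 and Gm10105 averaged 4.78 and 3.96 CPM, while Hmgn2 averaged 113 CPM against 184.6. The reads counted on these pseudogenes are therefore too few to account for the Hmgn2 fall. Reads placed at more than 1 position were not counted, so a loss of Hmgn2 reads in that way was not measured and stays open. The other 2 parents of called pseudogenes did not pass alone: Nudc was at -0.14 ± 0.13 alone and 0.04 ± 0.14 summed, and Rpl11 at 0.12 ± 0.15 alone and 0.22 ± 0.15 summed. A loss of reads from these 2 parents was therefore not seen, and one as small as the sums would restore is near their SE. The parent of Gm5824 was not found, and flanking DNA of another strain stays open as a hypothesis, since variants were not analysed here.

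Chromosome 3 stood 0.502 above the gene means in library KO 9 (log2 median over 568 genes). After a fit on GC content and gene length it stood at 0.515, which argues against these as the cause. The lower of the medians of its 2 parts, divided by gene order, stood at 0.501, which is consistent with a change along the whole chromosome, such as a copy gain, as a hypothesis. No biological explanation was tested. Chromosome 11 stood at 0.318 in WT 19, 0.237 in WT 23 and 0.187 in WT 13. Chromosomes 16 and 17 stood at 0.331 and 0.325 in WT 22. Chromosome 3 was also high in KO 10 and KO 6, at 0.427 and 0.217. It was below 0 in every WT library, and also in KO 3, KO 4, KO 5, KO 7, KO 8, KO 11 and KO 12. These medians are relative to each gene's mean over all libraries, which the high libraries raise. The group means differed by 0.133 for chromosome 3 and -0.0674 for chromosome 11 (permutation test, adjusted p = 0.299 and 0.399). The 4 calls on chromosome 3 were all higher and the 6 on chromosome 11 all lower in the libraries labelled KO. With chromosome medians as offsets, Ppp1r1b and Mprip were the only ones of these to pass. The second part of chromosome 4, which holds Nr0b2, stood at -0.528 in WT 21 and 0.286 in KO 12. Without WT 21, 9 of 301 genes within 10 Mb of Nr0b2 passed (odds ratio 20.95), and without KO 12, 13 of 298 (odds ratio 12.68), so the enrichment of calls there did not depend on either library. Over all fits leaving out single libraries the odds ratio ran from 12.33 to 46.62.

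For the count of genes, 1 of 100 splits of the 24 libraries, the real one, gave as many as 50. The highest of the others gave 2. This argues against chance for the count as a whole, which includes the calls tied to the Nr0b2 region. It does not decide the calls outside that region. Outside the Nr0b2 region, 3 of 100 splits gave as many as the 1 gene called, and the highest of the others gave 2. That share is under 0.05, but the gene is the pseudogene Gm5824, and at an unadjusted p under 0.05 another split gave 3124 genes against 2893.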
